A study of Mus musculus with 2 samples.

How the data were processed

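DNase-seq of mouse liver was available as 2 technical libraries of 1 biological replicate, and no group was compared with another. The deposited files were 3 peak lists, 1 hotspot list, 1 footprint list and 2 tracks of false discovery rate (FDR) per interval, all on mm10 per the labels. Per the notes deposited with both libraries, the files derive from 2 filtered alignments, called run A and run B here, and both alignments are listed for both libraries. No file was tied to a single library, and whether the technical libraries were pooled, the aligner, the peak caller and their versions are not given in the sources used here. Run A gave 1 peak list, the hotspots and 1 FDR track, and run B gave 2 peak lists, the footprints and the other FDR track.

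The deposited peak lists give a height per peak, read here as a signal that the authors scaled in a way not given in the sources used here. Run B heights were whole multiples of a single step of 0.00439 (100% of heights within 0.05 steps), and run A heights were whole numbers from 4 to 18703. If 1 step stands for 1 read, the median main peak holds 185 reads and the lowest 10% hold up to 52, but that reading is an assumption. Heights are the authors' own values and were used to describe, rank and filter peaks within a list. Between lists they were used only for the correlation and for the ratios of run A height to main height. The deposited FDR tracks hold an FDR for intervals up to 0.05. The deposited footprint list holds the same FDR value of 0.01 for every footprint, read as its threshold. The deposited hotspot list gives −log10 of the FDR, from 1.30 to 100, with 11442 hotspots at the upper limit. The deposited hotspot score is 10 times that value and was not used further. Of the hotspots, 52.9% had the borders of a run of bases up to FDR 0.05 in the run A track and 4.59% in the run B track.

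Coordinates were used on GRCm38 with the GENCODE M21 annotation (55413 genes, 21938 of them protein-coding, 141730 TSS entries). The build was checked against the sequence: 0 regions lay outside the 21 chromosomes, and 3 of 36917270 bases in main peaks were N. Positions are given counting from 1. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, bedtools 2.31.1 and BLAST 2.17.0. The gene lists, the consensus sequences, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except those said to be added after.

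The main peak list was set by rule as the list with the largest share of peaks inside the hotspots. Read as peaks lying wholly inside, this is the shorter run B list with 98.2%, against 85.5% for the longer run B list and 83.1% for run A. Read as peaks touching a hotspot by 1 bp, it would be run A with 99.9988%, against 99.3% for the main list. The literal reading was settled on after these overlaps had been counted, and the other lists were run as alternatives. Every peak of the main list held a base with a run B FDR of 0.001 or less.

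Peak lists were compared by overlaps of at least 1 bp. FDR tracks were compared by the share of bases up to 0.05 in either track that both held. Peaks overlapping the 1 kb on either side of any TSS by at least 1 bp were assigned to promoters. Other peaks were assigned by overlap, in this order, to exons and introns, and the rest to intergenic sequence. Shares were set against 100 shuffles of the peaks within their chromosomes (20 for alternatives). For each protein-coding gene, the height of the highest peak overlapping the 1 kb on either side of any TSS was taken, or 0 without a peak. An annotated TSS can lie inside the gene, so this peak is not always at the outer start of the gene. For each of 26 gene lists (323 genes in all, some in more than 1 list) the median over members was placed among 10000 random lists of equal size, matched on deciles of the promoter CpG observed over expected ratio. Percentiles describe this sample and are not p-values. The random lists at promoters were not matched on the number of annotated TSS per gene. A gene with more TSS has more windows in which a high peak can count. Peaks per 10 kb over the gene with 10 kb on either side, and members under the widest 1% of hotspots, were placed among random lists matched on gene length deciles. A list was called outside random lists beyond the central 95%, from 2.5 to 97.5%.

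Footprints lying in main peaks (394125) were widened by 5 bp on each side and scanned on both strands for 32 consensus sequences. The share with a match was divided by the share among windows of the same width in the same peaks that touched no footprint, which 98.2% of the footprints had. Errors are SE from leaving out each of 20 chromosomes in turn and are not the spread between animals. A ratio was called when its log2 lay more than 2 SE from 0. This log2 scale was chosen after the SE of the linear ratios had been seen, since ratios with few matched windows have skewed errors, and a counting interval was used where no finite SE could be had. Each consensus written backwards without complementing served as a control of base composition. Reversal keeps the base counts but turns each CpG into GpC, so it does not control for CpG content. Against 0 windows, ratios are lower bounds with a floor of 3 windows over the whole set.

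Named genes were all members of the clock list, and from each other list the 3 members with the highest promoter peak and up to 3 without a peak in alphabetical order. The 10 protein-coding genes with the highest promoter peaks, the genes nearest to the 10 highest distal peaks and those under the 10 widest hotspots were named as well. Genes on chromosome 18 were left out by the rule, and some genes that the rule names are not reported here. The highest and the fourth highest peak of the genome, the peak near Alkbh8, the genes sharing a promoter peak with a named gene, and the genes of the Y chromosome were named after their values had been seen.

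The code was tested on simulated data. Of 5000 simulated intervals, 3214 overlapped by 1 bp and 1181 by 50% reciprocally, the same counts that bedtools gave. Of 200 simulated lists of 12 genes, 3.5% fell outside the central 95% with heights unchanged, 41.5% with heights multiplied by 2 and 75% with heights multiplied by 4. A sequence planted in 20.0% of 9994 simulated footprints was found in 20.1% of them and in 0.0200% of background windows.

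Alternatives were the upper 50% of peaks by height, the other peak lists, peaks found in every list, promoter windows of 0.5 and 2.5 kb, flanks of 0 and 50 kb, random lists without matching and protein-coding transcripts only. Others were overlaps of 50% in both directions or centres within 75 bp, FDR thresholds of 0.01 and 0.001, autosomes only, and the widest 5% of hotspots or hotspots merged within 3 kb. Footprint margins of 0 and 10 bp and background windows placed 100 bp from the footprint were also run. Added after the data were seen were footprint density within 5 classes of peak height, chromosome densities in the other lists, clock sequences in promoter footprints, shared promoters, the counts of list members with a promoter peak and their percentiles under each alternative and the comparison of distal over promoter ratios with those of the reversed sequences. Promoter peaks of 4 Y genes were searched against X with blastn for matches of 30 bp or more at 95% identity or more, also after the data were seen. The interval of the lowest decile of height on chromosome 1, from 2000 draws, and the height ratios of the highest peaks between runs were added then as well. Further places of the highest peaks, and of these Y peaks, in the assembly were searched with blastn, at 90% identity over at least 80% of the peak.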

Results

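Accessible chromatin was mapped by DNase-seq in liver of adult C57BL/6J mice aged 8 to 10 weeks that had been kept in constant darkness for 70 h. DNase-seq sequences the ends left by the nuclease DNase I, which cuts DNA mainly where no nucleosome covers it. The labels place the tissue at Circadian Time 58 and give 1 biological replicate sequenced as 2 technical libraries. Circadian Time 58 would be hour 10 of a 24 h cycle if counted from the start of a cycle, but how it relates to the 70 h of darkness is not given in the sources used here. The study has no second time point and no other group, so the question addressed here is which genes, regions and sequences were accessible in this liver. With 1 biological replicate there was no replicate check, and no p-value across genes was computed. The read depth was not given in the sources used here.

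Accessible DNA took up a small part of the genome. The main peak list held 168636 peaks that covered 36.1 Mb, or 1.33% of the GRCm38 (mm10) genome, with a median width of 200 bp. A longer list from the same processing run, called run B here, held 228656 peaks over 48.8 Mb. The other run, called run A, gave 242348 peaks, nearly all 150 bp wide, over 36.3 Mb. Hotspots, the wider regions in which cut density exceeds the background, numbered 200129 and covered 98.9 Mb, or 3.63% of the genome, with a median width of 307 bp. Footprints, short stretches inside accessible DNA that are protected from cutting, numbered 514486 with a median length of 10 bp. Of the footprints, 78.1% touched a main peak and 98.6% touched a hotspot.

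The peak heights of the 3 lists ranked regions nearly alike, while the lists differed in how many weak peaks they held. Of the main peaks, 96.7% touched a run A peak and 98.2% touched a peak of the longer run B list. In the other direction, 67.5% of the run A peaks touched a main peak. Across the 163087 shared peaks the log2 heights of the main list and of run A correlated with Pearson's r = 0.999. That value is across regions of 1 sample, which are not independent replicates, and whether the runs used the same reads was not given in the sources used here. The 10th percentile of run A height over main height was 227.708, and 1 main height unit held 227.707 steps, as equal whole values in both runs would give. The runs may therefore share reads, and r is no measure of agreement between separate data. Bases with a false discovery rate up to 0.05 covered 97.7 Mb in run A and 93.2 Mb in run B, and the shared bases made up 87.9% of the bases in either. Requiring 50% of both peaks to overlap lowered the share of main peaks found in run A to 80.6%.

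Peaks were concentrated at gene starts. Of the main peaks, 24.3% overlapped the 1 kb on either side of an annotated transcription start site (TSS). Among peaks shuffled within chromosomes 6.90% did, a ratio of 3.52. The 95% Wilson interval of the observed share was 24.1 to 24.5%, which covers counting error only. Exons held 5.82% of the peaks (ratio 1.25), introns 40.0% (ratio 1.04) and intergenic DNA 29.8% (ratio 0.599). Promoter peaks were also the highest class, with a median height of 1.19 against 0.769 in exons, 0.742 in introns and 0.689 in intergenic DNA, in the deposited height units. The intron ratio lay close to 1 and fell to 0.967 when promoters were taken as 2.5 kb around each TSS. At least 1 promoter peak was found at 14239 of 21938 protein-coding genes, or 64.9%, with a median height of 3.46 for the highest peak.

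Every gene of the circadian clock list had a promoter peak. The highest promoter peaks among the 22 members stood at the nuclear receptor genes Nr1d2 (height 10.3) and Nr1d1 (9.67) and at the period gene Per1 (9.86), followed by the output regulator Dbp at 8.51. Cry2 stood at 8.07, Per2 at 8.03, Arntl at 8.01, Ciart at 7.83, Tef at 7.53, Hlf at 6.74 and Bhlhe40 at 6.28. Heights were 4.99 at Csnk1d, 4.29 at Per3, 3.64 at Cry1, 3.51 at Nfil3, 3.25 at Npas2 and 3.23 at Bhlhe41. The lowest heights of the list were 2.42 at Rora, 1.97 at Clock and 1.28 at Csnk1e. The highest peaks of Cry2, Tef, Hlf and Rora lay inside the genes, more than 1 kb from their outer start. They counted through other annotated TSS. The list median of 6.51 exceeded all 10000 random lists of equal size matched on promoter CpG content, whose median was 2.90 and whose central 95% ran from 1.18 to 4.50. These random lists were not matched on the number of TSS per gene.

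Both regulatory arms of the clock had a promoter peak at every member, but neither count lay outside matched random lists. The 11 genes driven mainly through E-boxes or D-boxes, the sites of the CLOCK and ARNTL proteins and of DBP-like factors, had a median of 7.83 at percentile 99.99 of matched random lists. The 6 genes driven mainly through ROR elements, the sites shared by ROR activators and NR1D repressors, had a median of 3.57 at percentile 76.5. Members with a promoter peak numbered 11 against a random mean of 9.28 (percentile 92.46 of the counts) and 6 against 4.51 (percentile 95.03). The difference between these lists was not itself tested. The Per1 peak lay on chromosome 11 at 69094761 to 69095260, at the start of the gene (69095217 to 69109960). The Nr1d1 peak lay on chromosome 11 at 98775241 to 98775700, and the gene runs from 98767932 to 98775333. The Nr1d2 peak lay on chromosome 14 at 18239081 to 18239380, the Per2 peak on chromosome 1 at 91459341 to 91459680, and the Dbp peak on chromosome 7 at 45704761 to 45705240. The Arntl peak lay on chromosome 7 at 113207081 to 113207460.

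**Figure D1:**
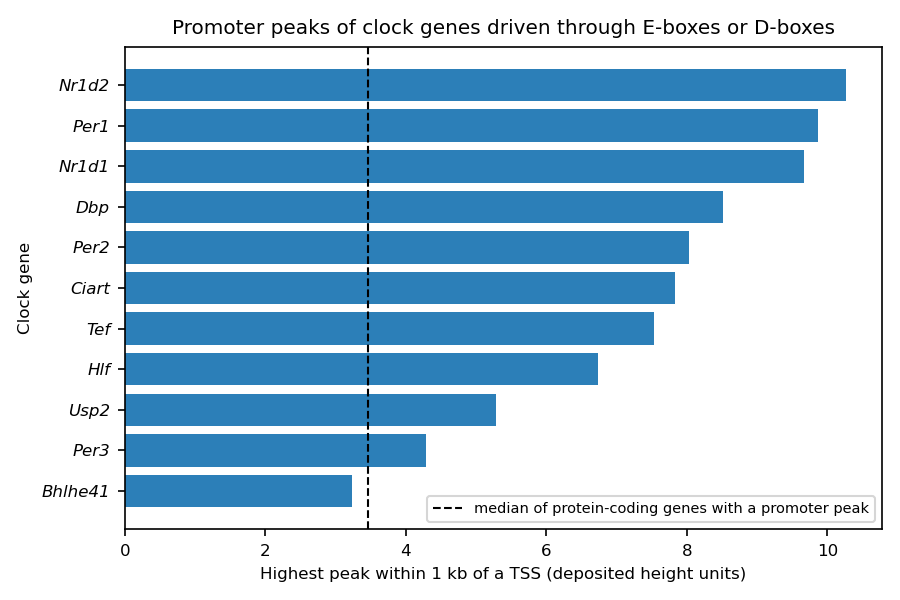
Height of the highest promoter peak (deposited height units, main peak list) of each of the 11 genes of the E-box and D-box list, with the median of all protein-coding genes that had a promoter peak as a dashed line at 3.46. The bars run from 3.23 at Bhlhe41 to 10.3 at Nr1d2, and 10 of the 11 lie above the line.

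Genes that carry out hepatocyte functions had accessible promoters in every list. All 27 genes of secreted plasma proteins had a promoter peak, against a mean of 11.2 in matched random lists, and their median height was 5.92 at percentile 100. The lipoprotein gene Apoa2 reached 10.97, the complement gene C3 8.69 and the fetuin gene Ahsg 8.47. All 20 hepatic transcription factor genes had a promoter peak (random mean 14.8), with a median of 5.85 at percentile 99.99. Esrra stood at 9.23, Nr5a2 at 8.80 and Ppara, the fatty acid sensor, at 7.92. Every member of the 4 metabolic lists had a promoter peak. The 14 bile acid and drug metabolism genes had a median of 4.46 (percentile 99.99), with Por, the electron donor of the microsomal cytochromes P450, at 10.0, the carboxylesterase gene Ces1d at 8.13 and Cyp2e1 at 6.76. The 16 glucose and glycogen genes had a median of 6.06 (percentile 100), with liver glycogen synthase, Gys2, at 8.61. The 14 urea cycle and amino acid genes had a median of 5.69 (percentile 100), with Tdo2 at 8.23, Asl at 7.44 and Gls2 at 7.28. The 20 lipid and cholesterol genes had a median of 5.98 (percentile 99.99), with Angptl4 at 10.97 and Cpt1a, the gate of mitochondrial fatty acid entry, at 8.92. The highest peaks of Ppara, Por, Asl, Angptl4 and Cpt1a lay inside the genes, more than 1 kb from their outer start, and counted through other annotated TSS.

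Genes of both ends of the liver lobule were accessible. All 10 periportal genes had a promoter peak, with a median of 5.81 at percentile 99.96, and Pck1 stood at 8.01, Gls2 at 7.28 and Arg1 at 6.89. All 10 pericentral genes had one too, with a median of 3.84 that lay at percentile 85.5, inside the central 95% of matched lists. Cyp2e1 stood at 6.76, Cyp1a2 at 5.70 and Oat at 5.53. The tissue was not separated by zone, and the difference between the zonal lists was not itself tested.

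Promoters of all male-biased liver genes of the list were accessible, and those of 6 of the 12 female-biased genes. All 10 male-biased genes had a promoter peak against a random mean of 3.56, and their median height was 3.06 (percentile 99.93), with the steroid enzyme gene Hsd3b5 at 5.23, Cyp2d9 at 5.20 and Ugt2b1 at 4.16. Of the 12 female-biased genes, 6 had a promoter peak against a random mean of 2.96 (percentile 98.3 of the counts), with a median of 0.143 at percentile 98.4. The difference between the male-biased and female-biased lists was not itself tested. The highest female-biased member was Cyp17a1 at 11.7, followed by A1bg at 1.91 and Hao2 at 0.360. The Cyp17a1 peak lay on chromosome 19 at 46668361 to 46668580, inside this minus-strand gene (46667165 to 46673172) and away from its outer start. It counted through an annotated TSS inside the gene. The Cyp2d9 peak (82452241 to 82452460) also lay inside its plus-strand gene, which starts at 82433437. No promoter peak was found at Cyp2b13, Cyp2b9 or Cyp3a41a. The labels do not give the sex of the animal. Among random lists not matched on CpG content the male-biased list lay at percentile 83.2 and the female-biased list at percentile 11.9, and with promoters of 0.5 kb on each side the female-biased list lay at percentile 49.1. The female-biased count lay at percentile 49.5 in the upper 50% of peaks by height, 95.4 with promoters of 0.5 kb and 15.5 without matching.

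Acute phase and immediate early genes had accessible promoters at this time point. All 14 had a promoter peak against a random mean of 7.90, with a median height of 4.10 at percentile 99.6. Crp, an acute phase protein gene, reached 10.9, the AP-1 subunit gene Jun 10.3 and Orm1 7.67.

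Marker genes of the other liver cell types had list medians from 0 to 0.553, and only the cholangiocyte median lay outside matched random lists, below them. Of the counts of members with a peak in the main list, the endothelial one lay above matched random lists and the cholangiocyte one below. Of 12 sinusoidal endothelial markers, 10 had a promoter peak against a random mean of 6.67 (percentile 97.6 of the counts), with a median height of 0.553 at percentile 56.6. That count was 3 against 5.21 (percentile 8.89) in the upper 50% of peaks by height, and without matching it lay at percentile 90.3. The scavenger receptor gene Stab2 stood at 3.67, Tie1 at 3.49 and Clec4g at 0.821, and Lyve1 and Pecam1 had none. Of 12 Kupffer cell and macrophage markers, 4 had a peak against a random mean of 3.26 (percentile 69.8 of the counts and 46.6 of the medians), with Fcer1g at 3.61, Cd68 at 0.940 and Spi1 at 0.518, and none at Adgre1, Cd5l or Clec4f. In run A and in the longer run B list, 11 of these 12 markers had a promoter peak, against random means of 3.92 and 3.85 (percentile 100 of the counts in both), and without matching the main count lay at percentile 1.64. Of 12 stellate cell and fibroblast markers, 6 had a peak (percentile 17.5 of the counts), with a median of 0.127 (percentile 12.1), Col1a1 at 2.67, Reln at 0.830 and Lrat at 0.426, and none at Acta2, Col3a1 or Colec11. Of 10 cholangiocyte markers, 4 had a peak against a random mean of 7.71 (percentile 0.525 of the counts and 0.450 of the medians, the former 5.15 in run A and 5.82 in the longer run B list), with Sox9 at 4.39 and Krt23 at 2.43, and none at Cftr, Cldn7 or Epcam. Of 12 lymphocyte markers, 4 had a peak (percentile 8.05 of the counts and 15.8 of the medians), with Lck at 2.46, Pax5 at 1.35 and Ptprc at 0.369, and none at Cd3e or Cd4. Of 12 erythroid markers, 3 had a peak (percentile 8.89 of the counts and 32.9 of the medians), with Alas2 at 0.615 and Epor at 0.457, and none at Ermap, Gata1 or Hba-a1.

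Genes of other tissues had a promoter peak in the main list at 50% or fewer of the members of each list. Of 15 posterior Hox genes, 3 had a promoter peak against a random mean of 12.9 (percentile 0 of the counts and 0.01 of the medians), with Hoxa10 at 0.567, Hoxc10 at 0.312 and Hoxd9 at 0.268, and none at Hoxa11, Hoxa13 or Hoxa9. Of 12 neuronal genes, 4 had a peak against 9.68 (percentile 0.015 of the counts and 0.095 of the medians), with Syn1 at 1.31, Snap25 at 0.922 and Rbfox3 at 0.913, and none at Grin1, Neurod1 or Slc17a7. In run A 9 of the 12 neuronal genes had a promoter peak and in the longer run B list 8, against random means of 10.2 and 10.1, counts inside the central 95%, while the median height stayed at percentiles 0.300 and 0.190. Of 12 germ cell and pluripotency genes, 3 had a peak against 8.19 (percentile 0.09 of the counts and 2.06 of the medians), and with promoters of 2.5 kb the count of 7 lay at percentile 10.6. Gdf9 had a height of 12.0, Dazl of 1.90 and Tnp2 of 0.386, and Ddx4, Nanog and Pou5f1 had none. The Gdf9 peak also lay within 1 kb of a TSS of Uqcrq, a gene of the respiratory chain. Of 12 skeletal muscle genes, 6 had a peak (percentile 10.8 of the counts), with a median of 0.160 (percentile 7.64), Mylpf at 7.13, Actn3 at 4.04 and Myh4 at 2.16, and none at Acta1, Mb or Myf5. Peaks of Mylpf and Actn3 also lay within 1 kb of a TSS of Tbc1d10b and Zdhhc24. Of 12 pancreas genes, 4 had a peak against 6.40 (percentile 4.72 of the counts and 12.1 of the medians), with Cela1 at 6.15, Ins2 at 3.32 and Nkx6-1 at 0.365, and none at Cel, Cpa1 or Ctrb1. The Cela1 and Ins2 peaks lay inside the genes and away from their outer start. Against random lists not matched on CpG content, the count lay at percentile 0.025 for posterior Hox genes (random mean 9.75), 0.300 for germ cell genes (7.79), 1.73 for neuronal genes (7.75) and 6.14 for cholangiocyte markers (6.46). A median of 0 could not fall outside the central 95% of unmatched lists, since their lower limit was 0. All 12 housekeeping genes had a peak, with a median of 6.12 (percentile 99.8), B2m at 7.33, Eef1a1 at 7.21 and Rpl13a at 6.97.

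**Figure D2:**
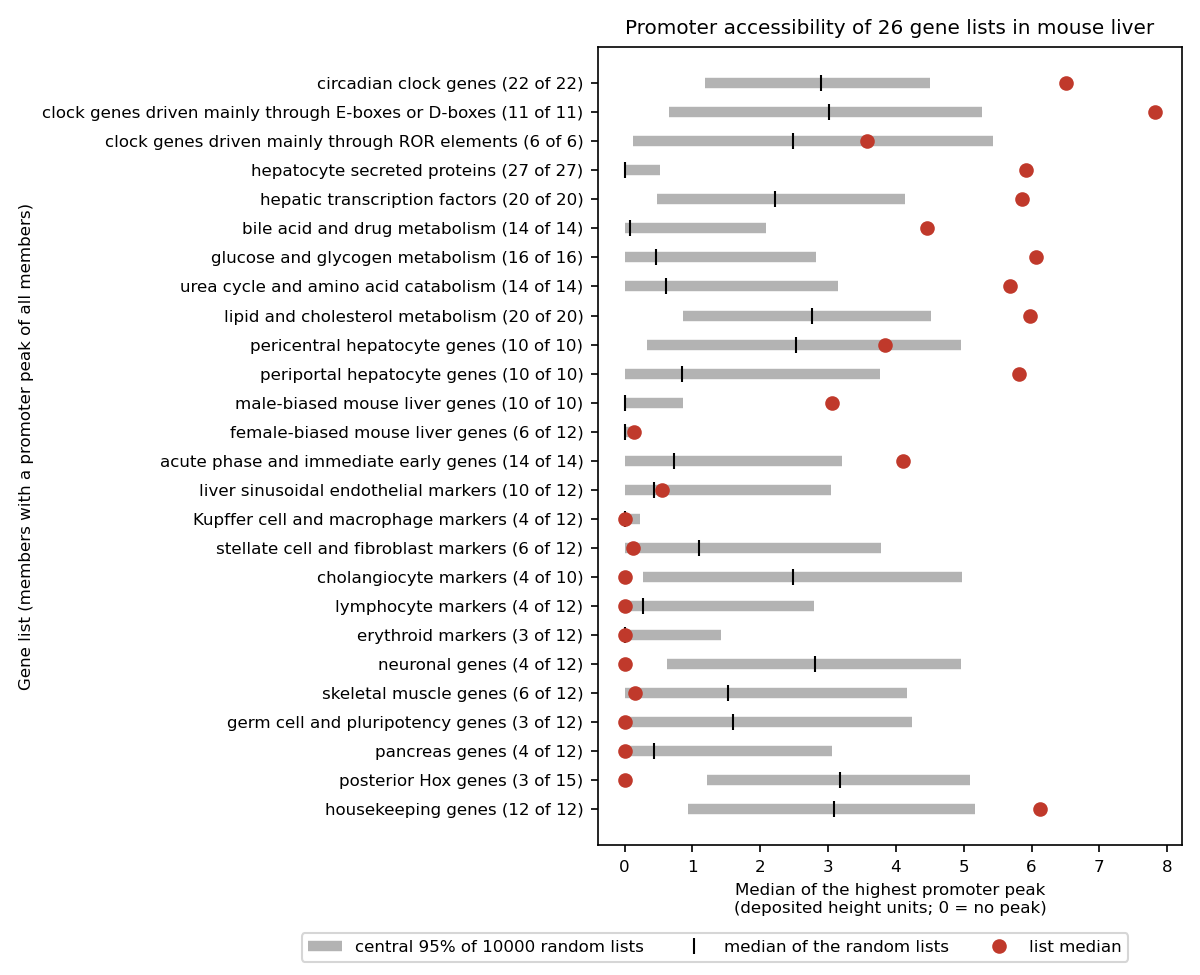
Median height of the highest promoter peak (deposited height units, 0 where a member has none) of 26 gene lists as red points, with the central 95% of 10000 random lists matched on CpG content as grey bars and their median as a black tick. The clock list stands at 6.51 and the secreted protein list at 5.92, while the posterior Hox list stands at 0.

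Hepatocyte genes also carried many peaks over their whole loci. Bile acid and drug metabolism genes had a median of 8.27 peaks per 10 kb of gene and flanks and secreted protein genes one of 7.90, against 1.101 and 1.14 in random lists matched on gene length. Values were 5.90 for hepatic transcription factors, 5.76 for periportal genes, 4.83 for glucose and glycogen genes, 4.80 for urea cycle and amino acid genes and 3.94 for lipid and cholesterol genes, all at percentile 100. Clock genes had 3.11 peaks per 10 kb (percentile 100) and pericentral genes 2.46 (percentile 99.6). Acute phase genes had 3.89, male-biased genes 3.19 and housekeeping genes 2.97. With flanks of 50 kb in place of 10 kb the pericentral list lay at percentile 82.4, and without flanks the male-biased list lay at percentile 89.5. Female-biased genes had 1.24 (percentile 63.4), endothelial markers 1.33 (percentile 81.0) and Kupffer cell markers 0.586 (percentile 7.74).

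Many of the widest hotspots lay over genes of liver function. The widest of all spanned 30748 bp on chromosome 19 (5821378 to 5852125), touched the protein-coding gene Frmd8, held the non-coding RNA gene Neat1, and contained 53 main peaks and 121 footprints. A hotspot of 17401 bp covered the pioneer factor gene Foxa2 (chromosome 2, 148032203 to 148049603). Hotspots of 15268 bp at the fibrinogen gene Fgb, 15039 bp at Apob, 14955 bp at Sdc4 and 14723 bp at Tsku followed. The remaining 4 of the 10 widest were at the heme synthesis gene Alas1 (14056 bp), the catalase gene Cat (13982 bp), the apolipoprotein genes Apoc1 and Apoe together (13943 bp) and the tyrosine aminotransferase gene Tat (13853 bp). The widest 1% of hotspots lay over 1661 protein-coding genes. Among these were 12 of 14 bile acid and drug genes against a random mean of 1.12, 20 of 27 secreted protein genes against 1.70, 13 of 16 glucose and glycogen genes against 1.19 and 15 of 20 transcription factor genes against 1.57. Of the 22 clock genes, 10 lay under such a hotspot against 1.86, and of the endothelial, Kupffer cell and stellate cell markers 0 did, against random means of 1.16, 0.885 and 0.972, too low for a count of 0 to fall outside the central 95%. Under the widest 5% of hotspots they were 0, 1 and 0 against 4.84, 3.66 and 4.15, at percentiles 0.100, 4.26 and 0.280.

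Of the 30 highest peaks of the genome, 9 lay within 76600 bp of chromosome 1, around Ugt1a1, Hjurp and Trpm8. The highest of all had a height of 75.9 and lay on chromosome 16 at 35981661 to 35981800, within 1 kb of the start of the non-coding gene Gm15564 and 1584 bp from that of Kpna1. The fourth highest, with a height of 49.0 in the main list and 1717 in run A, lay on chromosome 1 at 195241541 to 195241820. Its run A height was 35.1 times that in the main list, against 228 to 255 for 80% of shared peaks, and 11 of the 21 highest peaks outside the group of 9 lay outside that range. Among protein-coding promoters, the highest peak was shared by Hjurp and Trpm8, which start next to each other on chromosome 1. It had a height of 30.8 (88277501 to 88277760), and a peak at the bilirubin-conjugating enzyme gene Ugt1a1 in the same region had one of 19.7. Further high promoter peaks were at Ephx2 (14.1), Snrnp70 (13.7), Rpa2 (13.3), Zbtb5 (13.2), Hbp1 (13.05) and Grk4 (13.02). Away from promoters, the highest peak lay in an intron of Trpm8 (59.9, chromosome 1, 88288181 to 88288400), and 2 more in Trpm8 introns had heights of 31.4 and 24.1. A peak of 80 bp in an exon of the mitochondrial leucyl-tRNA synthetase gene Lars2 had a height of 59.1 (chromosome 9, 123461981 to 123462060). Others lay nearest to Pak3 on the X chromosome (39.9), Jarid2 (38.0), Ugt1a1 (22.8), Ide (20.3), Ddx18 (19.5, at a distance of 789222 bp) and Mroh2a (18.8). The Mroh2a peak touched no run A peak and no hotspot. A BLAST search placed it at 55 further positions of the assembly, the Lars2 peak at 6 and the highest peak of all at 2.

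Footprints were found in most peaks of either class. In promoter peaks there were 10.8 ± 0.0787 footprints per kb (chromosome-jackknife SE) and in distal peaks 11.1 ± 0.0317, and 78.4% of promoter peaks and 84.6% of distal peaks held at least 1. The promoter density over the distal density was 1.07 with promoters of 0.5 kb on each side of a TSS, 1.15 over run A peaks and 1.04 over the longer run B list, so the direction turned with the setting. The jackknife SE measures spread between chromosomes, not between animals.

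Many recognition sequences of liver regulators and of general promoter factors were more frequent in footprints than in nearby DNA of the same peaks, with FOXA, among others, as an exception. The sequence of CTCF, the insulator protein, occurred in 5128 footprints and in 32 of the matched windows, a ratio of 160 ± 35.1. Among regulators of hepatocytes, the direct repeat of nuclear receptors (DR1) had a ratio of 50.2, the C/EBP palindrome 28.4, HNF1 25.1 ± 7.94, NR5A2 8.41 ± 1.38, HNF4A 7.60 ± 0.784 and HNF6 4.30 ± 0.142. The DR1, C/EBP and HNF1 ratios rested on 6, 10 and 7 matched windows. NRF1 sequences occurred in 341 footprints and 0 windows, at least 114-fold more with a floor of 3 windows over the whole set. NFI was at 146 against 0 (at least 48.7-fold) and REST at 46 against 0 (at least 15.3-fold). RFX occurred in 49 footprints and 1 window, a ratio of 49.0 with a counting interval from 8.39 to 1974. The cyclic AMP response element (CRE) had a ratio of 21.2 ± 5.24, YY1 4.47 ± 0.953, ETS 2.69 ± 0.215 and SP/KLF 13.03 ± 1.07, whose sequence is the same when reversed. NFY had a ratio of 1.27 ± 0.0861, which was 1.11 and within 2 SE of 1 with unwidened footprints. ZNF143 had a ratio of 1.88 ± 0.732, within 2 SE of 1, and was called above 1 with 10 bp margins and with windows 100 bp away (7.25).

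Ratios depended on the footprint margin and on where the windows lay, while each sequence named in this paragraph stayed above 1 under the settings that gave a finite ratio. CTCF ranged from 68.6 to 478, DR1 from 25.1 to 238, the C/EBP palindrome from 28.4 to 70.0, NR5A2 from 6.15 to 18.2, HNF4A from 5.14 to 14.9, HNF6 from 3.24 to 7.30 and RFX from 17.0 to 49.0. CRE ranged from 18.6 to 63.6, SP/KLF from 9.57 to 33.6 and ETS from 2.17 to 6.19, and HNF1 rose to 44.5.

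Sequences that clock proteins can bind were enriched in footprints too, though the scan does not show which protein was bound. The consensus of the C/EBP-like D-box takes in every match of the D-box and of the C/EBP palindrome. Their ratios are therefore nested and do not tell clock factors from C/EBP. The D-box had a ratio of 7.45 ± 0.569, the related C/EBP-like D-box 5.63 ± 0.169, the E-box 3.57 ± 0.188 and the ROR element 1.37 ± 0.176. Over the settings the D-box ranged from 5.02 to 14.4, the C/EBP-like D-box from 4.05 to 11.2, the E-box from 2.64 to 5.75 and the ROR element from 1.13 to 2.35. E-boxes occurred in 1.03% of footprints and in 0.288% of windows. In all, 23 of 32 sequences lay above a ratio of 1 by more than 2 SE on the log2 scale. FOXA (0.444 ± 0.0232) and GATA (0.289 ± 0.0388) lay below it, and stayed below 1 under all settings, from 0.191 to 0.745 and from 0.0629 to 0.489. Within 2 SE of 1 were 7, among them AP-1 (0.976), the glucocorticoid receptor (0.971), MEF2 (1.00) and MYOD (0.954). With footprints widened by 10 bp in place of 5 bp the ROR element ratio was 1.13, within 2 SE of 1, while MEF2 (1.45) and the glucocorticoid receptor (1.68) lay above 1. AP-1 lay below 1 with unwidened footprints (0.770 ± 0.0538) and above 1 against windows 100 bp away from each footprint (1.37), where MYOD had a ratio of 1.18. DNase I cuts some sequences more readily than others, which was not corrected for here. The reversed sequences control for base composition, and not for CpG content or this cutting preference. Of the 25 sequences with finite ratios of both, 21 had a higher ratio than their own reverse. That count takes no account of error and includes small differences such as MYOD (0.954 against 0.941). Outside these 25, SP/KLF is the same when reversed, and 6 could not be compared, among them CTCF, whose reverse occurred in 2 footprints and 0 windows.

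**Figure D3:**
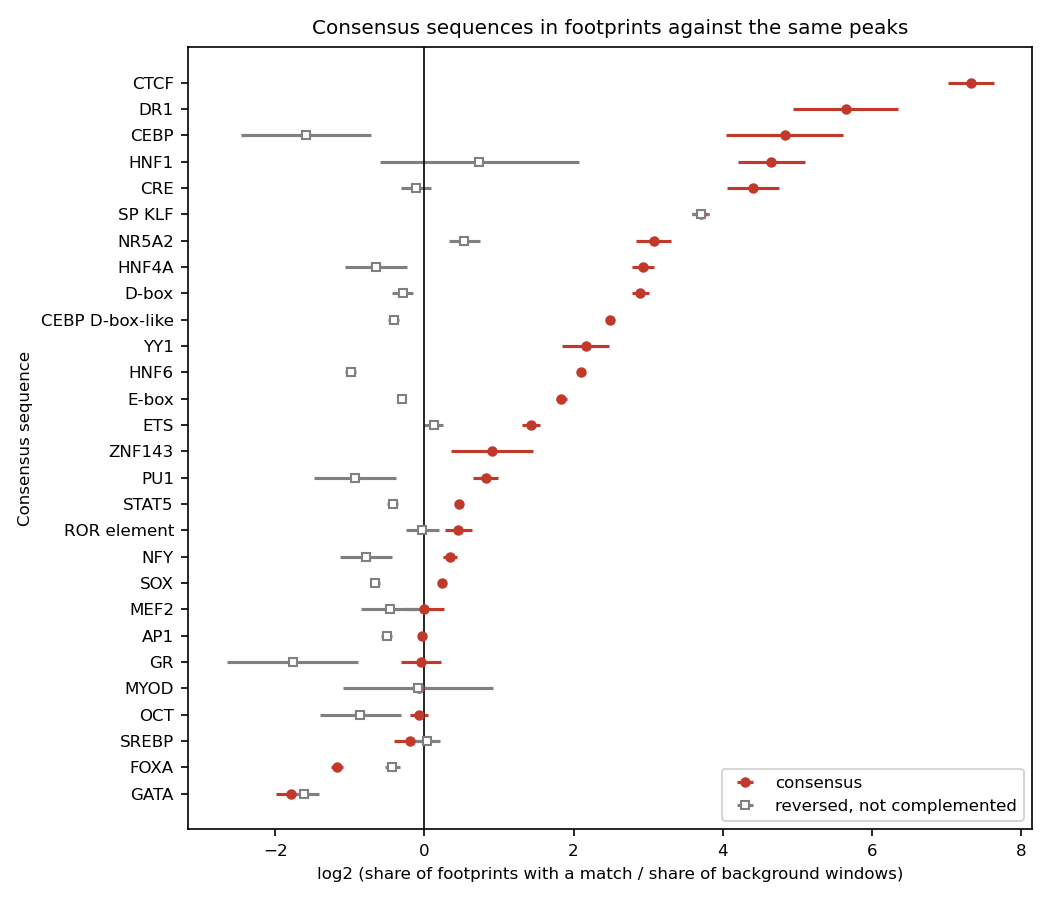
Log2 ratio of the share of footprints with a consensus sequence to the share of matched windows in the same peaks, for 28 of 32 sequences with a finite ratio and SE (red) and 24 of their reversed forms (open squares). Bars are 1 chromosome-jackknife SE, and the vertical line marks a log2 ratio of 0; CTCF lies highest and GATA lowest.

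Sequences of general factors were more frequent in promoter footprints, and those of most liver regulators in distal footprints, where their ratios lay within 2 SE of those of their reversed sequences if these could be compared. The share of distal footprints with a sequence over that of promoter footprints was 0.0359 ± 0.0150 for YY1, 0.0522 ± 0.00625 for NRF1, 0.0715 ± 0.00443 for SP/KLF, 0.0822 ± 0.00819 for ETS, 0.190 ± 0.0185 for NFY and 0.214 ± 0.0182 for CRE. The reversed sequences of ETS (1.48), NFY (0.868) and CRE (1.71) had higher ratios by more than 2 SE. The E-box was also more frequent in promoter footprints, with a ratio of 0.651 ± 0.0204 against 0.996 for its reverse. The ETS, CRE and E-box sequences hold a CpG that their reverses lack. Their comparison with the reverse therefore cannot separate factor sites from the CpG content of promoters, which was not tested. The C/EBP palindrome had a ratio of 0.712 ± 0.105, which lay within 2 SE of 1 (0.839) with promoters of 2.5 kb. In the other direction, CTCF had a ratio of 2.63 ± 0.0982, with too few matches of its reverse for a comparison. HNF6 had a ratio of 3.06 ± 0.173 (reverse 2.32 ± 0.310), NR5A2 2.46 ± 0.235 (1.61 ± 0.337), FOXA 2.40 ± 0.254 (2.38 ± 0.441), HNF4A 2.35 ± 0.181 (1.45 ± 0.553) and AP-1 2.27 ± 0.169 (1.87 ± 0.124). Among clock sequences, the ROR element had a ratio of 3.11 ± 0.758 (reverse 3.24 ± 0.808) and the D-box 2.07 ± 0.159 (2.74 ± 0.420). In all, 16 sequences were more frequent in distal and 10 in promoter footprints by more than 2 SE. Of the 16, 12 lay within 2 SE of their own reverse, 1 lay below it and 3 could not be compared, and of the 10, 4 lay below their reverse, 5 could not be compared and SP/KLF is the same when reversed. Promoter footprints numbered 105063 and distal footprints 289062.

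Peak density varied between chromosomes and was lowest on the sex chromosomes. Autosomes held 68.6 main peaks per Mb of known sequence, from 53.7 on chromosome 14 to 100.3 on chromosome 19. The X chromosome held 25.6 per Mb, a ratio of 0.373 to the autosomes. The Y chromosome held 53 peaks, or 0.601 per Mb. How much of each chromosome reads could be placed on uniquely was not assessed. A low density, above all on Y, therefore need not mean low accessibility. The ratio of X to autosomes was 0.411 in the longer run B list and 0.419 in run A.

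**Figure D4:**
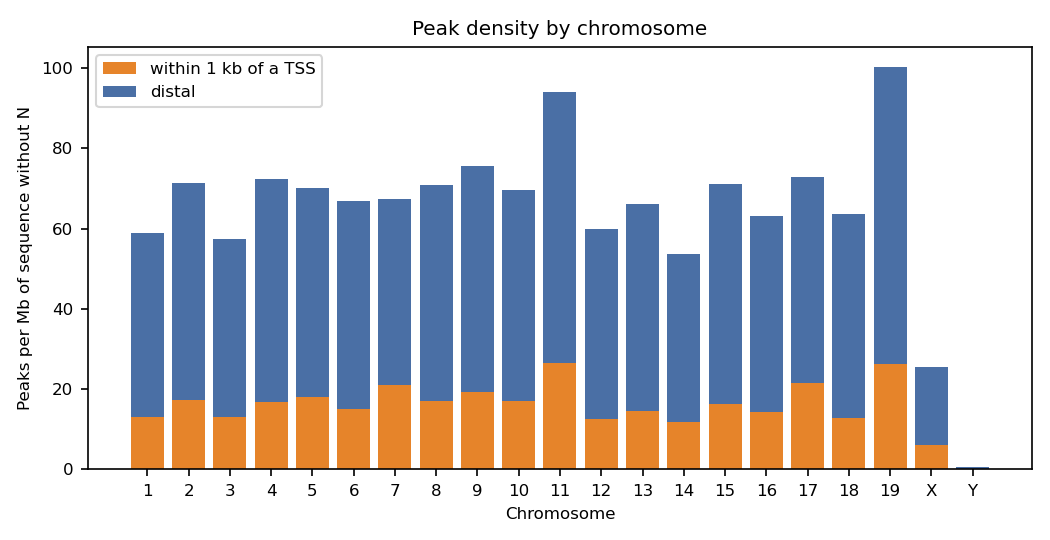
Main peaks per Mb of sequence without N on each chromosome, split into peaks within 1 kb of a TSS (orange) and distal peaks (blue). The X chromosome stands at 25.6 and chromosome 19 at 100.3.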

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

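Of 1000 alternative values, 884 were labelled unchanged, 38 moved, 18 turned in direction, 30 lost a call and 30 gained one. Counts and the X ratio were labelled unchanged within a fixed fold range of the main value, and overlap shares within their counting interval. The FDR thresholds of 0.01 and 0.001 were labelled moved without a rule. The footprint densities in the 5 height classes could only be labelled moved or turned. Values with a call rule were labelled unchanged if the call stayed the same. Those without a call in either setting were labelled so even where the direction turned. The footprint densities within 5 classes of height and the chromosome densities in other peak lists were alternatives chosen after seeing the data. The clock list stayed at or above percentile 98.8 at promoters and at percentile 100 over loci under every alternative run. Where a value changed, the cause was not tested, except that the upper 50% by height holds fewer regions by construction, 84335 peaks and 100072 hotspots. Overlap of the main list with run A was 80.6% by 50% in both directions, 91.9% by centres and 99.8% in the upper 50% of both lists. The share of run A peaks found in the main list was 56.1%, 63.8% and 69.5% under the same settings, and that of main peaks in the longer run B list was 90.3%, 96.2% and 99.96%. Shared bases of the FDR tracks were 87.5% at 0.01 and 86.9% at 0.001. The intron ratio was 0.967 with promoters of 2.5 kb and 0.971 in the upper 50% by height. Outside the central 95% at promoters were 17 lists, and 11 without CpG matching. Without matching, percentiles were 83.2 for male-biased, 11.9 for female-biased, 4.89 for cholangiocyte, 4.41 for neuronal, 4.27 for germ cell and 5.92 for posterior Hox genes. In the upper 50% by height they were 49.9 for female-biased, 2.98 for cholangiocyte and 9.74 for germ cell genes. With promoters of 0.5 kb they were 49.1 for female-biased and 3.53 for germ cell genes, the latter 4.19 with 2.5 kb. For 7 of these lost calls the list median was 0 and the lower limit of the random lists was 0 too, so the median could not lie outside, and in 5 of the 7 the count of members with a peak still did. The counts in these 7 lay at percentiles 3.75 (cholangiocyte) and 0.160 (germ cell) in the upper 50%, 0.025 (germ cell) with 0.5 kb, and 6.14 (cholangiocyte), 1.73 (neuronal), 0.300 (germ cell) and 0.025 (posterior Hox) without matching. Members with a promoter peak were 11 and 11 of the Kupffer, 9 and 8 of the neuronal genes in run A and the longer run B list, and 5 of the posterior Hox genes in run A. In the upper 50% by height they were 3 for endothelial, 2 each for female-biased, Kupffer, stellate, lymphocyte and pancreas, 1 for erythroid and 0 for posterior Hox genes. With promoters of 0.5 kb they were 2 for Kupffer, 1 for neuronal and 2 for pancreas genes, and with 2.5 kb 10 for stellate, 7 for neuronal and 7 for germ cell genes. Percentiles of the counts changed call for female-biased (49.5 in the upper 50%, 95.4 with 0.5 kb, 15.5 without matching), pericentral (96.4 in run A, 96.6 in the longer run B list, 96.2 with 2.5 kb), endothelial (8.89 in the upper 50%, 90.3 without matching) and Kupffer cell genes (100 in run A and in the longer run B list, 1.64 without matching). They did for cholangiocyte (3.75 in the upper 50%, 5.15 in run A, 5.82 in the longer run B list, 6.14 without matching), stellate (0.280 in the upper 50%), lymphocyte (1.42 without matching), erythroid (1.56 in the upper 50%, 0.335 without matching) and neuronal genes (17.6 in run A, 6.12 in the longer run B list). They also did for germ cell (10.6 with 2.5 kb) and pancreas genes (1.11 in the upper 50%, 2.02 in run A, 2.24 in the longer run B list, 0.255 with 0.5 kb, 1.63 without matching). Clock genes of the E-box and D-box list (97.9 in the upper 50%, 99.6 without matching) and of the ROR list (98.3 in the upper 50%) and housekeeping genes (98.0 and 99.7) gained a call. Without a call, the side of percentile 50 changed for Kupffer (46.6 in the upper 50%, 28.3 with 0.5 kb, 46.6 with 2.5 kb) and stellate cell genes (50.5 in run A, 77.3 in the longer run B list, 90.8 with 2.5 kb). Over loci, percentiles were 82.4 for pericentral and 97.6 for endothelial genes with 50 kb flanks, 89.5 for male-biased genes without flanks, 2.08 for lymphocyte markers without matching, and 0.865 for Kupffer and 0.470 for stellate cell markers in the upper 50% by height. With the widest 5% of hotspots, percentiles were 96.6 for pericentral, 88.1 for male-biased, 1.78 for female-biased, 0.100 for endothelial and 0.280 for stellate cell genes, and with merged hotspots 91.6 for housekeeping genes. Promoter over distal footprint density was 1.07 with promoters of 0.5 kb, 1.15 in run A, 1.04 in the longer run B list, and 0.736, 0.579, 0.594, 0.894 and 1.13 from the lowest to the highest of 5 height classes of nearly equal size. With unwidened footprints 6 sequences lay below 1 by more than 2 SE, and PU.1 (0.385) and SOX (0.763) turned. AP-1 (0.770) and the OCT sequence (0.719) gained a call with unwidened footprints. GR (1.68) turned and MEF2 (1.45) gained a call with 10 bp margins, and AP-1 (1.37) and MYOD (1.18) with windows 100 bp away.

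The upper 50% of footprints was not run because every footprint has the same FDR value, and leaving out a technical library was not run because no file is tied to a library. No paired analysis was possible because the libraries form 1 group and no file is tied to either. Depth is not given in the sources used here, so how many weak peaks it leaves uncalled is unknown: the lowest main peak stands at 8 height steps and 10% of main peaks at or below 52.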

Other observations

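The tests on X distal peaks, on the match of Y promoter peaks to X and to the rest of the assembly, on the reverse of the FOXA and GATA sequences, on clock sequences in promoter footprints and on shared promoters were chosen only after the result was seen. E-boxes were frequent at the promoters of clock genes, whether counted inside footprints or anywhere in peaks with a footprint. Of the 22 clock genes, 11 had a footprint with an E-box within 1 kb of a TSS, against a mean of 1.70 and a central 95% of 0 to 4 in CpG-matched random lists (percentile 100). Tef had 4 such footprints, Per1 and Ciart 3 each, Hlf and Nr1d2 2 each, and Bhlhe41, Cry1, Dbp, Nfil3, Npas2 and Nr1d1 1 each. An E-box footprint was found at 1 of 27 secreted protein genes, 1 of 12 housekeeping genes and 5.72% of all protein-coding genes. Anywhere in peaks with a footprint, 13 of the 22 clock genes had an E-box, against a random mean of 3.09, and 10.2% of all protein-coding genes. Parts of the clock list were chosen as genes driven through E-boxes, D-boxes or ROR elements, so these counts are not independent of that choice. The random lists were not matched on accessibility and include genes without a promoter peak. Clock genes held from 7 (Csnk1e) to 33 (Dbp) promoter footprints each, so the excess is not separated from their number of footprints. D-boxes inside footprints were found at Per2 (2), Per3 (2) and Nr1d2 (1), 3 of 22 clock genes against a random mean of 0.260, and anywhere in such peaks at 4 against 0.426. ROR elements inside footprints were found at 0 of the 22, where the random mean was 0.0177, and anywhere in such peaks at 3 against 0.110 (percentile 99.98).

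High promoter peaks in the lists of other tissues and of blood were few. Of their 87 members, 27 had a promoter peak and 5 had one over a height of 3. Of these 5, Gdf9, Mylpf and Actn3 shared the peak with the start of another protein-coding gene, and Ins2 and Cela1 did not. The Ins2 and Cela1 peaks lay inside the genes, more than 1 kb from their outer start, and counted through other annotated TSS. Across all 27, 4 peaks were shared in this way, the other at Hoxc10 with Hoxc5.

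The sex chromosomes held few peaks, and the Y chromosome held 53, of which 19 lay within 10 kb of 4 genes that all had promoter peaks, with heights of 1.70 at Kdm5d, 1.87 at Eif2s3y, 3.75 at Uty and 1.97 at Ddx3y. Reads from X are unlikely as the source of these promoter peaks, since 2.48% of the bases of the 7 peaks matched X over 30 bp or more at 95% identity, with at most 17.0% in a single peak. Fewer gene promoters on X could not be the whole account of its low density, since distal peaks were also rarer there (19.5 per Mb) than on any autosome (41.9 to 74.2 per Mb). X promoter peaks had 0.538 times the median height of CpG-matched autosomal promoter peaks (0.469 to 0.591), as a single X copy per cell might give. Tissue of females alone, with 1 active X, is unlikely, since all 4 Y genes had a promoter peak that matched neither X nor a further place in the assembly, while a mix of sexes was not tested and the sex is not in the labels.

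The highest peaks clustered: 9 of the 30 highest lay within 76600 bp of chromosome 1 (88211801 to 88288400), around Ugt1a1, Mroh2a, Hjurp and the start of Trpm8, and 1 of the 9, near Mroh2a, had 55 further places in the assembly and no run A peak. Reads from other copies in the assembly are unlikely as the main source of the other 21, since 14.3% of them (4.98 to 34.6%), namely the highest peak, the Lars2 peak and the peak near Alkbh8, had a further place there, against 1.67% of 300 random peaks. Copies missing from the assembly were not tested, and in 11 of the 21 the height in run A over that in the main list lay outside 228 to 255, the range that held 80% of shared peaks, from 35.1 to 856. Extra copies of the chromosome 1 locus might account for the cluster: the lowest decile of height of its 44 peaks was 3.93 times (2.67 to 5.26) that of the peaks within 300 kb, and the median height of its 35 other peaks was 2.49 times theirs (1.44 to 4.29). Dense strong regulation of the locus stays open as well, since no DNA copy number was analysed here and no biological explanation was tested.

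FOXA and GATA sequences were rarer inside footprints than in the rest of the same peaks. A shortage of such sites in accessible DNA is unlikely, because distal peaks over shuffled positions, divided by the same ratio for the reverse sequence, gave 2.08 for FOXA (1.96 to 2.20) and 1.71 for GATA (1.52 to 1.92). Before that division the ratio was 1.37 ± 0.0260 for FOXA and 1.13 ± 0.0512 for GATA, and 0.658 and 0.659 for their reverses. Much of both values thus came from the low reverse, most of all for GATA. Base composition could account for GATA, whose log2 ratio differed from that of its reverse by -0.17 ± 0.28. It could not account for all of the FOXA value, where the difference was -0.74 ± 0.13. It could account for a part, since the reversed FOXA sequence had a ratio of 0.742 against 0.444 for FOXA. For FOXA it stays open whether short residence on DNA, cutting preference of DNase I or the footprint caller keeps sites out of footprints, and none of these was tested.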
